A study of Mus musculus with 24 samples.

How the data were processed

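Frontal cortex of 24 mice was profiled by bulk RNA sequencing of poly-A selected RNA. Per the labels, mice heterozygous for a targeted progranulin gene (Grn+/-) were crossed with mice carrying a human TDP-43 transgene (hTDP) to give littermates of 4 genotypes, and 6 mice of each genotype were sampled at different ages, 3 females and 3 males per genotype. Per the labels' protocols, brains were perfused with saline and frozen before the frontal cortex was dissected, RNA was fragmented after poly-A selection, and cDNA was primed with random hexamers. The protocol text describes library steps that keep strand and steps that do not, so which kind these libraries are is not clear, and overlapping genes on opposite strands may share reads. Mice were 8.19 to 10.79 months old: 9.44 to 10.79 months in Grn+/+ mice without the transgene, 8.19 to 10.79 months in Grn+/- mice without it, and 9.44 to 10.07 months in both transgenic groups. Each library is a separate mouse.

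The deposited files hold 1 Salmon quantification per library over 149444 transcripts, of which 1 is a human TARDBP transcript and the rest are mouse transcripts. Per the file headers, the authors' values are expected counts (estimated reads per transcript, which need not be whole), TPM (length-corrected transcript abundances scaled to the same total in every library) and effective transcript lengths. The submitters' processing notes name STAR, SAMtools, Salmon and DESeq2 without versions or roles. The genome build and annotation release are not given in the sources used here. Transcript identifiers, without their version numbers, were looked up in the GENCODE M21 annotation of GRCm38. This placed 138032 transcripts (92.4%) in 52352 genes, and coordinates are those of GRCm38 in that annotation. The other 11411 mouse transcripts held 1.17% to 1.66% of the reads of a library and were left out of the gene tests; they were tested separately as transcripts. Libraries held 61445842 to 100859149 estimated reads.

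Deposited expected counts were summed per gene and rounded to whole numbers. Genes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), two-sided, with TMM scaling, edgeR's default filter on low counts, and a model with 1 term per genotype and a term for sex over all 24 libraries. All 4 groups thus shared an estimate of the spread. Of the genes, 18239 passed the filter. The comparisons were the transgene in each Grn genotype, the Grn genotype with and without the transgene, both changes against neither, the interaction (the transgene effect in Grn+/- minus that in Grn+/+), the average transgene effect, the average Grn effect, and the transgene effect in males against females. Adjusted p-values are Benjamini-Hochberg values, and a gene was called at an adjusted p under 0.05. CPM values are counts scaled by TMM-adjusted library size, computed from the deposited expected counts, and log2 values used a prior count of 1. Levels of Grn, mouse Tardbp, Thy1 and human TARDBP were compared between groups of 6 by exact two-sided permutation tests over all 924 splits. With 6 against 6, the smallest p these can give is 0.0021645.

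Transcript usage, the share of a gene's reads assigned to each of its transcripts, was tested over 7876 genes with edgeR's likelihood-ratio fit and its diffSpliceDGE function, combining transcripts by Simes' method and keeping transcripts with at least 5% of their gene. Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 34 lists of a comparison, with the result at an estimated correlation beside it. The 34 lists are the transgene and target genes (Grn, Tardbp, Thy1); lysosomal genes; homeostatic and activated microglia; complement; reactive astrocyte genes; markers of astrocytes, oligodendrocytes, oligodendrocyte precursors, excitatory neurons, deep layer projection neurons, inhibitory neurons, endothelium, mural and meningeal cells, choroid plexus and ependyma, striatal neurons and olfactory bulb; blood cell genes; neurofilament and axon genes; synaptic genes; immediate early genes; neuropeptides; interferon response genes; integrated stress and unfolded protein genes; heat shock genes; p53 and DNA damage genes; RNA-binding protein genes; long-intron and splicing targets of TDP-43; cholesterol synthesis genes; mitochondrially encoded genes; oxidative phosphorylation genes; cytosolic ribosomal protein genes; and sex chromosome genes as a check of the labels. Within a list, counts "adjusted over the list alone" use Benjamini-Hochberg values over its measured members.

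Groups, comparisons, models, lists and the other settings to be tried were fixed before the data were examined. Genes named in each comparison are Grn, Tardbp and Thy1, then called genes with a mean CPM of at least 1 and a symbol that is not a provisional identifier, up to 12 with the highest and 12 with the lowest log2 change. Where fewer than 5 genes were called, the 5 genes of smallest p are given as values. Up to 4 members of smallest p are named per list, and for transcript usage the 10 genes of smallest adjusted p and members of the splicing target list. Some items that this rule selects are not reported here. Called genes outside this rule are named as such, and were chosen after their values were seen.

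The other settings tried for the gene tests were DESeq2 1.42.0, RLE scaling, no filter on low counts, a filter of CPM 1 in 6 libraries, age as a linear term, age as a factor, surrogate variables (sva 3.50.0), length-scaled TPM counts, limma voom with sample weights, no sex term, a fit to only the 2 groups compared, and leaving out each library. For transcript usage they were limma's diffSplice, minimum shares of 10% and of 0, age, and no sex term, and for lists an estimated correlation, the fry test, age, and no sex term. Levels were also compared as TPM, with age and with DESeq2. Added after seeing the data were usage and lists without replicate 2 of the transgenic Grn+/+ mice, usage with a quasi-likelihood fit, and the splicing target list without Tardbp and without Mapt. Tables were handled with Python 3.11.15 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.

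The tests were tried on simulated counts with the means and library sizes of the real libraries and, for the gene tests, 50 changed genes per size of change. For the average transgene effect, edgeR recovered 44% of genes changed 1.15-fold, 68% of those changed 1.25-fold, 88% at 1.5-fold and 100% at 2-fold. It made 13 false calls, against 32 for DESeq2 and 14 for voom. For the interaction, edgeR recovered 4%, 20%, 68% and 88% at these folds, with 5 false calls. For the average Grn effect the recovered shares were 40%, 78%, 90% and 98%. The usage test recovered 20 of 67 genes with shifts of 5 percentage points (29.9%) and 47 of 67 with shifts of 10 (70.1%). It made 26 false calls (limma 53, quasi-likelihood fit 36), so its adjusted p-values overstate the evidence. Counts of usage calls may thus hold false calls and also miss small shifts. No library was left out of the main comparisons. Replicates of the same genotype differed by far more than sampling noise: the smallest chi-square per degree of freedom between them was 18.1 over 9813 genes. No library thus appears to have been deposited again within its genotype. Pairs across genotypes were not tested in this way. In 0 of 24 libraries did the sex chromosome genes go against the labelled sex.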

Results

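The transcriptome of the frontal cortex was measured in 24 mice of 4 genotypes, with 6 mice per genotype and 3 of each sex. The mice carried 2 or 1 working copies of Grn, the gene of the lysosomal and secreted glycoprotein progranulin, and either carried or lacked a transgene for human TDP-43, an RNA-binding protein encoded by TARDBP. The series title puts the question of whether loss of progranulin and excess TDP-43 act on each other. Libraries held 61445842 to 100859149 estimated reads. At this depth the median standard error of a log2 change, over genes above 10 CPM, was 0.0564 for a comparison of 6 with 6 mice, 0.0399 for an average over both backgrounds and 0.0798 for the interaction. The transgenic Grn+/+ library of replicate 2 held 97736984 reads but listed 40188 transcripts above 0, against 65994 to 69846 in the other libraries, and 17669 genes above 0, against 22269 to 23272.

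Human TARDBP reads were present in every transgenic library and nearly absent from the others. The human transcript reached 34.9 ± 1.98 TPM (SD, n = 6) in transgenic Grn+/+ mice, from 5067 to 6933 reads per library, and 34.4 ± 3.86 TPM (n = 6) in transgenic Grn+/- mice, from 4328 to 8162 reads. Libraries without the transgene held 0 to 2 such reads. The transgenic groups differed in human TARDBP by less than the spread between mice (exact two-sided permutation p = 0.786, n = 6 per group). Endogenous mouse Tardbp (chromosome 4, 148612382 to 148627019) was lower in both transgenic groups. It measured 146 ± 2.78 CPM in Grn+/+ mice without the transgene and 103 ± 6.93 CPM with it, a ratio of 0.704 (exact permutation p = 0.0021645, the smallest possible, n = 6 per group). In Grn+/- mice it measured 144 ± 4.73 and 99.7 ± 9.21 CPM, a ratio of 0.693 (exact permutation p = 0.0021645, n = 6 per group). The 12 transgenic libraries lay between 91.1 and 116 CPM and the 12 others between 137 and 150.5 CPM. Human and mouse transcripts added up to 0.856 of the nontransgenic Grn+/+ TPM in transgenic Grn+/+ mice and to 0.810 of it in transgenic Grn+/- mice. That sum depends on the modelled length of the human transcript, whose untranslated parts may differ from those of the transgene. In counts the sum went the other way. Averaged over both Grn genotypes, mouse Tardbp lost 43.8 CPM while the human transcript held 74.8 ± 5.67 CPM (SD, n = 12).

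Grn (chromosome 11, 102430315 to 102437048) was lower in heterozygous mice on either background. It measured 51.0 ± 7.34 CPM in Grn+/+ and 25.9 ± 6.23 CPM in Grn+/- mice without the transgene, a ratio of 0.507, and 47.9 ± 8.10 and 26.7 ± 5.29 CPM with it, a ratio of 0.558 (exact permutation p = 0.0021645 for each, n = 6 per group). The 12 heterozygous libraries ranged from 13.8 to 32.9 CPM and the 12 Grn+/+ libraries from 34.7 to 60.5 CPM. The transgene left Grn within the spread between mice, with exact permutation p = 0.485 in Grn+/+ and p = 0.779 in Grn+/- mice (n = 6 per group). Thy1, a neuronal surface glycoprotein gene, stood at 699 ± 12.2, 701 ± 41.2, 696 ± 28.9 and 708 ± 30.2 CPM (n = 6 each) in Grn+/+ mice without and with the transgene and in Grn+/- mice without and with it. Its average log2 change with the transgene was 0.01 (SE 0.03).

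**Figure D1:**
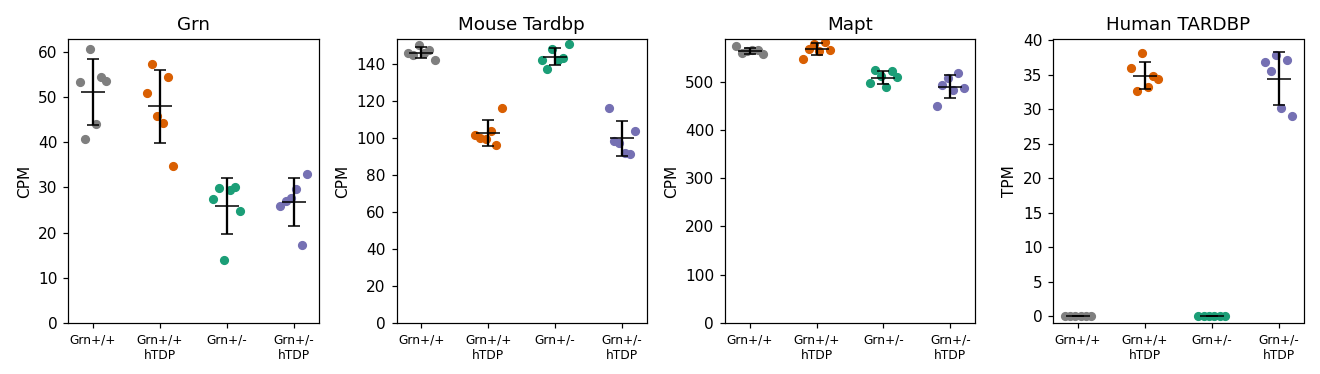
Levels of Grn, mouse Tardbp and Mapt (CPM) and of human TARDBP (TPM) in the 4 genotypes, with 1 dot per library and bars for mean and SD (n = 6). Mouse Tardbp lies between 91.1 and 116 CPM in transgenic libraries and between 137 and 150.5 CPM in the others, and Grn and Mapt are lower in both Grn+/- groups.

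The average transgene effect over both Grn genotypes asks what human TDP-43 changed in the cortex whichever Grn genotype the mouse had. Of 18239 genes, 20 were called, 6 higher and 14 lower, with the endogenous Tardbp gene as the gene of smallest p (log2 change −0.52, SE 0.0351, edgeR adjusted p = 6.86e-09). Gid4 (chromosome 11, 60417145 to 60450927), the substrate receptor of the CTLH ubiquitin ligase, rose from 74.5 ± 3.94 to 89.8 ± 4.24 CPM (n = 12 each, edgeR adjusted p = 2.20e-05). Spop (chromosome 11, 95414080 to 95493406), a substrate adaptor of cullin ubiquitin ligases, rose from 207.6 ± 4.56 to 234.8 ± 8.79 CPM (n = 12, edgeR adjusted p = 0.000128). Atp6v0e2 (chromosome 6, 48537615 to 48541801), a membrane subunit of the proton pump that acidifies lysosomes and synaptic vesicles, fell from 362 ± 9.30 to 312 ± 10.8 CPM (n = 12, edgeR adjusted p = 1.15e-05). Tmem8b, a transmembrane protein gene (chromosome 4, 43668971 to 43692668), fell from 113.5 ± 6.25 to 94.7 ± 4.59 CPM (n = 12, edgeR adjusted p = 0.000140). For Gid4, Atp6v0e2 and Tmem8b the 12 libraries with and the 12 without the transgene did not overlap.

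The other genes that fell with the transgene act in varied processes. The insulin receptor gene Insr went from 52.6 ± 2.28 to 44.8 ± 3.60 CPM (n = 12, edgeR adjusted p = 0.00946), and Bsn, the gene of the presynaptic scaffold bassoon, from 854 ± 78.1 to 706 ± 68.4 CPM (edgeR adjusted p = 0.0373). Lower with smaller log2 changes were the kinesin motor gene Kif3c (−0.13, edgeR adjusted p = 0.00623), Ap2m1, of the clathrin adaptor of endocytosis (−0.11, 0.0251), and the serine/threonine phosphatase gene Ppm1a (−0.12, 0.0141). Scrn1, a secernin (−0.17, 0.0141), and Clns1a, which takes part in assembling spliceosomal ribonucleoproteins (−0.12, 0.0467), fell as well. Pot1a, a telomere-binding protein gene (chromosome 6, 25743737 to 25809246), fell from 13.7 ± 0.945 to 10.9 ± 1.06 CPM (n = 12, edgeR adjusted p = 0.00531), and Trbc2, a T cell receptor constant segment, from 13.4 ± 2.71 to 8.53 ± 1.81 CPM (0.0251). Among genes that rose, Rarres2, the gene of the chemoattractant chemerin, gained 0.78 on the log2 scale (edgeR adjusted p = 0.00946) at a low level of a few CPM. Tcte1, a sperm flagellum gene, went from 3.93 ± 0.711 to 5.42 ± 0.547 CPM (0.0248), the zinc finger gene Zfp180 from 57.3 ± 3.72 to 69.0 ± 5.28 CPM (0.00623) and the mitochondrial gene Rcc1l from 10.9 ± 0.668 to 12.6 ± 0.565 CPM (0.00870). Gm16485 (log2 change −0.42) and Gm49593 (−0.30) were also called and are named after their values were seen. Of the 20 genes, 5 lie on chromosome 6, which holds 922 of the 18239 genes tested and was singled out after the values were seen. Where age entered the model as a factor, a fit in which 4 of the 6 nontransgenic Grn+/- mice have ages that no other group holds and so inform no comparison between genotypes, Tardbp and Atp6v0e2 kept their calls and the other 18 lost them with their sign kept: Gid4 stayed at 0.27 (edgeR adjusted p = 0.152), Spop went from 0.18 to 0.17 (0.354) and Trbc2 from −0.65 to −0.84 (0.354). Leaving out 1 library ended the call of Clns1a in 19 of 24 fits, of Bsn and Gm49593 in 18, of Ap2m1 in 12, of Tcte1 in 8 and of Trbc2 in 7. DESeq2 called 61 genes and surrogate variables gave 41. Surrogate variables ended the calls of Bsn and Clns1a, voom that of Bsn, and linear age those of Clns1a and Gm49593. Without a filter Clns1a, Ppm1a and Ap2m1 lost theirs. With length-scaled TPM counts 13 of the 20 kept their calls: Ppm1a turned to 0.065 (adjusted p = 0.556), and its transcripts shifted in use, as given with the transcript usage, while Rarres2 (0.0704), Pot1a (0.0818), Bsn (0.417), Clns1a (0.155), Ap2m1 (0.111) and Gm49593 (0.0704) lost theirs with their sign kept.

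**Figure D2:**
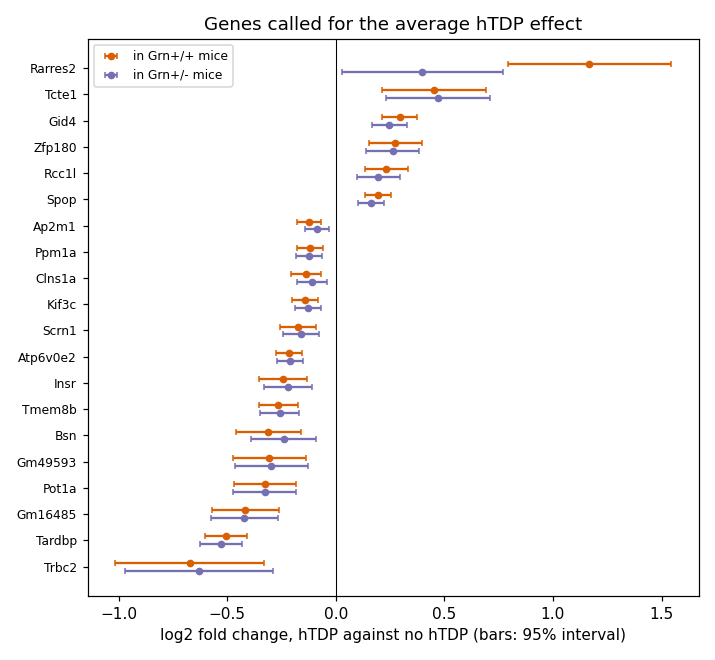
Log2 change with the transgene, with 95% intervals, of the 20 genes called for the average transgene effect, estimated separately in Grn+/+ (orange) and Grn+/- (purple) mice, n = 6 per group. Each gene points the same way on both backgrounds, and the interval of Rarres2 is wide.

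Synaptic genes lay lower, and ribosomal protein genes, oligodendrocyte markers and mural and meningeal markers higher, in the average over transgenic mice. Of 30 synaptic genes 28 had a negative log2 change (median −0.06; camera adjusted p = 1.02e-05), with Bsn called, Syn1 at −0.09 and the GABA receptor gene Gabrb2 at −0.17. The call was lost at an adjusted p = 0.269 with an estimated correlation. All 34 cytosolic ribosomal protein genes were above 0 (median 0.07; camera adjusted p = 8.10e-15, adjusted p = 0.354 with an estimated correlation). Their mean centred log2 CPM went from −0.084 to 0.032 with the transgene in Grn+/+ mice, and from 0.009 to 0.043 in Grn+/- mice (n = 6 each). All 19 oligodendrocyte markers were above 0 (median 0.22, with Mal at 0.32, Cldn11 at 0.30 and Hapln2 at 0.31, camera adjusted p = 0.000234, adjusted p = 0.657 with an estimated correlation). Their mean centred log2 CPM went from −0.25 to 0.38 with the transgene in Grn+/+ mice, but from −0.01 to −0.13 in Grn+/- mice (n = 6 each). The mural and meningeal markers (median 0.23, 16 of 16 above 0, adjusted p = 0.000510), among them the pericyte genes Rgs5 (0.11) and Vtn (0.15), were lost at an adjusted p = 0.471 with an estimated correlation. Of 13 mitochondrially encoded genes 12 were above 0 (median 0.09, with mt-Nd6 at 0.14 and mt-Co1 at 0.10, adjusted p = 1.59e-05, adjusted p = 0.292 with an estimated correlation).

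Known splicing targets of TDP-43 lay slightly lower as a list in transgenic mice, most of them without a call of their own. Of 20 genes fixed as known splicing targets of TDP-43, 17 had a negative log2 change (median −0.05; camera adjusted p = 1.37e-08, adjusted p = 0.00558 with an estimated correlation). With Tardbp in the list, this call held at both correlations. Adjusted over the list alone, 3 were lower: Tardbp itself, the MAP-kinase activating protein gene Madd (−0.10) and the ubiquitin ligase gene Herc2 (−0.17). Without Tardbp the list kept an unadjusted p of 0.000227, and 0.0195 with an estimated correlation. Of 19 long-intron targets 16 were below 0 (median −0.06, with the neurexin gene Nrxn3 at −0.10, the potassium channel gene Kcnma1 at −0.09 and Cadps, of vesicle release, at −0.11, adjusted p = 0.000234, adjusted p = 0.269 with an estimated correlation). The 3 transgene and target genes were called through Tardbp (adjusted p = 2.34e-10, adjusted p = 5.46e-05 with an estimated correlation).

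The remaining lists called for the average transgene effect lost their calls with an estimated correlation. Immediate early genes, which respond to neuronal activity, were below 0 in 17 of 17 (median −0.22, with Egr1 at −0.28; camera adjusted p = 0.00531, adjusted p = 0.685 with an estimated correlation). Cholesterol synthesis genes were below 0 in 17 of 18 (median −0.04, with Hmgcs1 at −0.09; 0.000437, adjusted p = 0.435 with an estimated correlation), and excitatory neuron markers in 14 of 14 (median −0.04; 0.0277, adjusted p = 0.435 with an estimated correlation). The mean centred log2 CPM of excitatory markers went from 0.041 to −0.060 with the transgene in Grn+/+ mice, but from 0.014 to 0.005 in Grn+/- mice. For cholesterol synthesis genes it went from 0.044 to −0.050 and from 0.012 to −0.005 (n = 6 each). Reactive astrocyte genes were above 0 in 16 of 20 (median 0.12; 0.00548, adjusted p = 0.471 with an estimated correlation), and choroid plexus and ependymal markers in 7 of 8 (median 0.41; 0.0277, adjusted p = 0.269 with an estimated correlation). The mean centred log2 CPM of these choroid plexus and ependymal markers went from −0.31 ± 0.25 to 0.36 ± 0.67 with the transgene in Grn+/+ mice (highest library 1.51). In Grn+/- mice it went from −0.03 ± 0.63 to −0.02 ± 0.44 (n = 6 each). Reactive astrocyte genes rose on both backgrounds, from −0.22 to 0.03 in Grn+/+ and from 0.04 to 0.15 in Grn+/- mice. Endothelial markers were above 0 in 10 of 13 (median 0.05; 0.0472, adjusted p = 0.655 with an estimated correlation) and oxidative phosphorylation genes in 19 of 29 (median 0.02; 0.0472, adjusted p = 0.819 with an estimated correlation). No call was made for lysosomal genes (camera adjusted p = 0.803), homeostatic microglia (0.617), activated microglia (0.617), complement (0.464), astrocytes (0.464), oligodendrocyte precursors (0.464), deep layer neurons (0.507), inhibitory neurons (0.507), striatal neurons (0.130) or olfactory bulb (0.682). The same held for blood (0.103), neurofilament and axon (0.574), neuropeptide (0.512), interferon (0.738), integrated stress and unfolded protein (0.738), heat shock (0.682), p53 and DNA damage (0.226), RNA-binding protein (0.512) and sex chromosome genes (0.738). Gpnmb, a glycoprotein gene of phagocytic microglia that lies on chromosome 6 (49036546 to 49070929) near called genes, had a log2 change of −0.67 (edgeR adjusted p = 0.265; 0.0186 adjusted over the list alone).

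The mix of transcripts shifted within the Ppm1a and Tardbp genes in transgenic mice. For Ppm1a the main coding transcript went from 58.7% ± 1.39 to 49.6% ± 1.85 of the gene's reads (n = 12 each), a transcript subject to nonsense-mediated decay from 12.9% ± 0.964 to 16.8% ± 1.28, and a retained-intron transcript from 18.2% ± 0.659 to 21.7% ± 1.41 (edgeR usage test adjusted p = 4.69e-22; limma 7.75e-19; 0.0802 with the quasi-likelihood fit). For Tardbp the nonsense-mediated decay transcript with the spliced 3' untranslated region went from 7.35% ± 0.902 to 14.2% ± 4.56 (n = 12; edgeR adjusted p = 2.66e-07; limma 0.000358). Mapk14, the p38 stress kinase gene, raised its main transcript from 58.4% ± 3.10 to 67.0% ± 4.41 (edgeR adjusted p = 0.00177; limma 2.60e-05). Slc25a44, a mitochondrial carrier, had a transcript that went from 13.2% ± 1.11 to 16.8% ± 0.965 (edgeR adjusted p = 7.71e-05, against 0.0739 with limma). Usage calls numbered 14 of 7876 genes, against 44 with limma and 1 with the quasi-likelihood fit, and 7 of the 14 were also called with limma: Cadm3, Lpin3, Luc7l2, Mapk14, Pkib, Ppm1a and Tardbp. The quasi-likelihood fit called 0 of the 14, with adjusted p = 0.0625 for Tardbp, 0.216 for Mapk14 and 1 for Slc25a44. Others of small p were the protocadherin Pcdhgc4 (edgeR adjusted p = 6.84e-13; limma 0.306), the endocytic GTPase Dnm1 (3.48e-06; limma 0.0640), Nat8f1 (0.00118; limma 0.560), and the low-abundance genes Cd36 (0.00361; limma 0.0587) and Lpin3 (0.0144; limma 0.00267). Of the splicing target list, Poldip3, Adnp2, Slc6a6, Ube3c and Mapt were not among the genes tested for usage. Among the members tested, Tardbp alone was called. Pdp1 (edgeR adjusted p = 0.638), Sort1 (0.948) and Dnajc5 (1) were not.

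**Figure D3:**
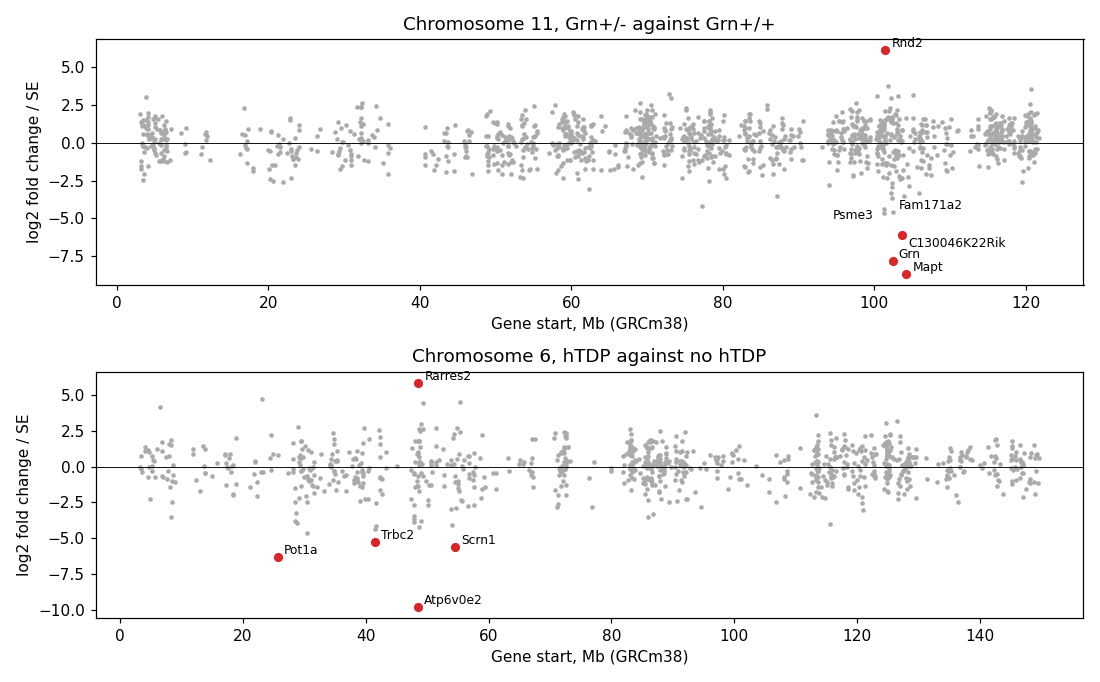
Log2 change divided by its standard error against gene start (Mb, GRCm38), with 1 point per tested gene, on chromosome 11 for the average Grn effect and chromosome 6 for the average transgene effect. Red points have an adjusted p under 0.05, and on chromosome 6 they number 5 of the 20 genes called for the transgene.

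On each Grn background taken alone, the transgene changed a small set of genes. In Grn+/+ mice 6 genes were called: Tardbp (log2 change −0.51, edgeR adjusted p = 1.04e-05), Atp6v0e2 (−0.22, 0.00259) and Tmem8b (−0.26, 0.0220) lower, and Rarres2 (1.17, 0.0117), Gid4 (0.29, 0.00259) and Spop (0.19, 0.00889) higher. In Grn+/- mice 4 genes were called: Tardbp (−0.53, 4.55e-06), Atp6v0e2 (−0.21, 0.00528), Tmem8b (−0.26, 0.0440) and Gid4 (0.25, 0.0281). All 6 genes of the first set had the same sign in the second, and 4 were called in both, against 0.00132 for independent lists. That figure takes every gene as equally likely to be called. Tardbp follows the genotype and both comparisons share an estimate of the spread, so the figure is no measure of chance overlap here. Gm16485, next by p, was at −0.42 in Grn+/- mice (edgeR adjusted p = 0.0669). Rarres2 went from 1.72 ± 0.272 to 3.86 ± 1.26 CPM in Grn+/+ mice and from 2.21 ± 0.622 to 2.91 ± 0.345 CPM in Grn+/- mice (n = 6 each). Its call in Grn+/+ mice was lost without replicate 4 of the nontransgenic Grn+/+ group (log2 change 1.08, edgeR adjusted p = 0.0568). Also in Grn+/+ mice, Tmem8b lost its call in 8 of 24 fits that left out 1 library and both Tmem8b and Spop lost theirs with age as a factor (adjusted p = 0.137 and 0.0898) and with length-scaled TPM counts (0.265 and 0.294), Spop also without a filter (0.0518). In a fit to these groups alone Tardbp was the 1 gene called, with Tmem8b at 0.108 and Rarres2 at 0.174. In Grn+/- mice the calls of Tmem8b and Gid4 were lost in 17 and 11 of 24 fits that left out 1 library, and with age as a factor all 4 were lost (0 called with edgeR, 207 at an unadjusted p under 0.05), with Tardbp at −0.54 (adjusted p = 0.259) and the nontransgenic Grn+/- group entering that comparison through its replicates 2 and 3 alone. Gid4 and Tmem8b lost theirs in Grn+/- mice also without a filter, with linear age, with length-scaled TPM counts and, as did Atp6v0e2, in a fit to these groups alone. DESeq2 called 29 genes in Grn+/+ and 10 in Grn+/- mice, and surrogate variables gave 13 and 9. Log2 changes on both backgrounds correlated at r = 0.246 over genes above 10 CPM and at r = 0.0313 over all genes tested. The rank correlation over all genes was 0.172. Genes are not independent replicates.

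Oligodendrocyte markers stood higher with the transgene in Grn+/+ mice (median log2 change 0.66, 19 of 19 above 0; camera adjusted p = 7.87e-12, adjusted p = 0.267 with an estimated correlation), and were at −0.18 in Grn+/- mice, without a call (camera adjusted p = 0.0914). TDP-43 splicing targets had a median of −0.08 in Grn+/+ mice (camera adjusted p = 2.12e-05, adjusted p = 0.0594 with an estimated correlation) and of −0.03 in Grn+/- mice (1.84e-06, adjusted p = 0.0197 with an estimated correlation). Without Tardbp, a member of the list, the unadjusted p with an estimated correlation was 0.0526 and 0.0534 on these backgrounds. Interferon response genes had a median of 0.18 in Grn+/+ mice (camera adjusted p = 0.00845, adjusted p = 0.529 with an estimated correlation) and of −0.16 in Grn+/- mice (0.00711, adjusted p = 0.679 with an estimated correlation).

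The average Grn effect asks what loss of 1 Grn copy changed in the cortex with or without the transgene. Besides Grn itself (log2 change −0.91, SE 0.117, edgeR adjusted p = 0.000614), 3 genes were called, all on chromosome 11 within 5 Mb of Grn. Mapt, the gene of the microtubule-associated protein tau (104231390 to 104332090), fell from 565 ± 9.37 to 499 ± 21.002 CPM (n = 12 each, edgeR adjusted p = 0.000215), with Grn+/+ libraries between 546.7 and 582 CPM and Grn+/- libraries between 449.5 and 525 CPM. Rnd2, a small GTPase gene of neuronal migration (101464999 to 101471853), rose from 60.95 ± 4.49 to 69.9 ± 3.52 CPM (n = 12, edgeR adjusted p = 0.0157). C130046K22Rik, outside the naming rule and chosen after its values were seen (103697724 to 103722832), fell from 2.57 ± 0.462 to 1.44 ± 0.400 CPM (n = 12, edgeR adjusted p = 0.0157). Psme3, a proteasome activator, was next at −0.09 (edgeR adjusted p = 0.424). DESeq2 called 9 genes and surrogate variables gave 7. Where age entered as a factor, with the nontransgenic Grn+/- group again entering through replicates 2 and 3 alone, only Grn was called: Mapt stood at −0.17 and Rnd2 at an adjusted p of 0.0649. C130046K22Rik lost its call there and with length-scaled TPM counts (−0.74, adjusted p = 0.910).

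By background, Grn (log2 change −0.98) and Rnd2 (0.28) were called without the transgene (edgeR adjusted p = 0.0440 for each), and Mapt (−0.21, edgeR adjusted p = 0.00517) with it. Mapt stood at −0.15 without the transgene (edgeR adjusted p = 0.247) and Grn at −0.84 with it (edgeR adjusted p = 0.254), with C130046K22Rik at −0.997 (edgeR adjusted p = 0.254) and Coa3, a mitochondrial assembly factor, at −0.14. Other values of small p without the transgene were the inositol phosphate kinase gene Ip6k3 (0.78, edgeR adjusted p = 0.689) and Gm13031 (0.69). Leaving out 1 library ended the call of Grn without the transgene in 19 of 24 fits and of Rnd2 in 18, and the number of calls was 0 in 17 (622 genes at an unadjusted p under 0.05 with all libraries, edgeR). Both calls were lost with age as a linear term or a factor and in a fit to these groups alone. With the transgene the call of Mapt held in all such fits and was lost without a filter, with age as a factor (adjusted p = 0.0630), with length-scaled TPM counts (0.638) and in a fit to these groups alone (0.876).

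Microglial genes lay slightly higher and deep layer neuron markers slightly lower in Grn+/- mice. Of 20 activated microglia genes 18 were above 0 (median 0.16, with the lipid carrier gene Apoe at 0.13, the receptor gene Trem2 at 0.15 and its adaptor Tyrobp at 0.16; camera adjusted p = 9.10e-05, adjusted p = 0.292 with an estimated correlation). From Grn+/+ to Grn+/- mice their mean centred log2 CPM went from −0.10 ± 0.17 to 0.14 ± 0.43 without the transgene. With it the values were −0.10 ± 0.16 and 0.06 ± 0.17 (n = 6 each). Homeostatic microglia markers were above 0 in 13 of 15 (median 0.09; 0.000164, adjusted p = 0.313 with an estimated correlation) and complement genes in 10 of 11 (median 0.13; 0.0231, adjusted p = 0.381 with an estimated correlation). Of 17 deep layer markers 15 were below 0 (median −0.11, with the transcription factor genes Fezf2 at −0.14 and Bcl6 at −0.15; camera adjusted p = 1.30e-05, adjusted p = 0.154 with an estimated correlation). Lysosomal genes, whose products work where progranulin acts, had a median of 0.02 and no call (camera adjusted p = 0.363), with the tetraspanin gene Cd63 at 0.15 and the glucuronidase gene Gusb at 0.12. Without the transgene 30 of 44 lysosomal genes were above 0 (median 0.03; camera adjusted p = 0.0116, adjusted p = 0.400 with an estimated correlation).

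Blood cell genes and mural and meningeal markers lay higher in Grn+/- mice under the preset correlation. Blood cell genes had a median of 0.97 (6 of 7 above 0, 5 higher adjusted over the list alone, with the globin gene Hbb-bt at 1.17; camera adjusted p = 0.00273, adjusted p = 0.313 with an estimated correlation), and mural and meningeal markers a median of 0.23 (15 of 16 above 0; 0.00273, adjusted p = 0.493 with an estimated correlation). Mitochondrially encoded genes were above 0 in 13 of 13 (median 0.09; 6.76e-07, adjusted p = 0.176 with an estimated correlation), with mt-Nd3 at 0.23 and mt-Nd5 at 0.11 higher adjusted over the list alone. Ribosomal protein genes were above 0 in 34 of 34 (median 0.05; 5.75e-07, adjusted p = 0.493 with an estimated correlation). Astrocyte markers (median 0.06; 0.00783, adjusted p = 0.493 with an estimated correlation) and reactive astrocyte genes (median 0.17; 0.0151, adjusted p = 0.493 with an estimated correlation) lay higher. Oligodendrocyte markers were below 0 in 19 of 19 (median −0.09, camera adjusted p = 0.0246, adjusted p = 0.780 with an estimated correlation). From Grn+/+ to Grn+/- mice their mean centred log2 CPM rose from −0.25 to −0.01 without the transgene and fell from 0.38 to −0.13 with it. TDP-43 splicing targets (median −0.02, with Mapt a member; 0.00129, adjusted p = 0.154 with an estimated correlation), long-intron targets (−0.05; 0.000363, adjusted p = 0.259 with an estimated correlation), RNA-binding protein genes (−0.02; 0.000106, adjusted p = 0.154 with an estimated correlation), synaptic genes (−0.01; 0.0222, adjusted p = 0.493 with an estimated correlation) and neurofilament and axon genes (−0.01, with Mapt a member; 0.0311, adjusted p = 0.324 with an estimated correlation) lay lower. The sex chromosome genes had a median of 0.04 (0.0222, adjusted p = 0.313 with an estimated correlation). Of the 18 lists called, the transgene and target genes alone, through Grn, kept their call (camera adjusted p = 4.91e-06, adjusted p = 0.00214 with an estimated correlation).

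**Figure D4:**
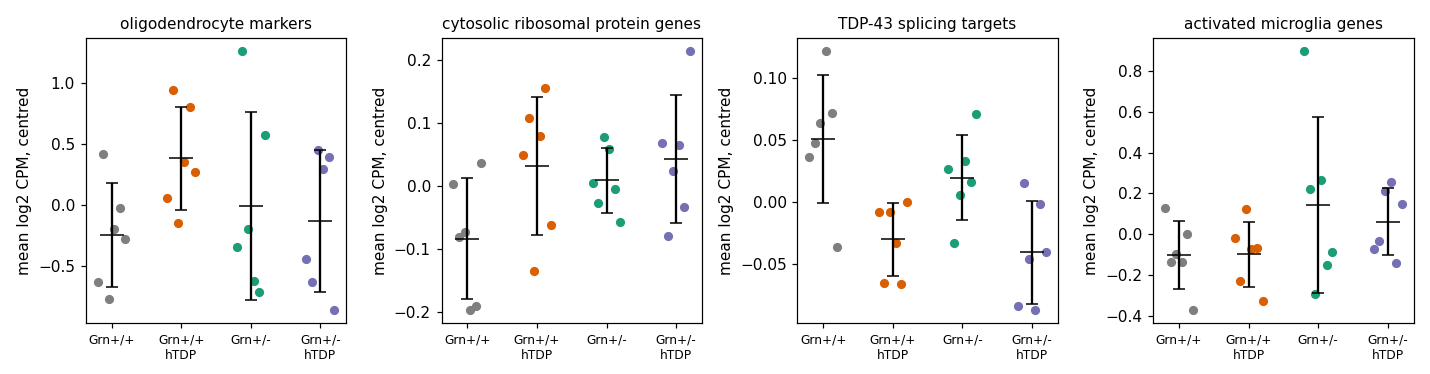
Mean centred log2 CPM of 4 gene lists (oligodendrocyte markers, cytosolic ribosomal protein genes, TDP-43 splicing targets, activated microglia genes), with 1 dot per library and bars for mean and SD (n = 6 per genotype). Splicing targets, Tardbp included, lie lower in both transgenic groups, and the spread between mice is wide for oligodendrocyte and microglial genes.

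The interaction asks whether the transgene acted differently in Grn+/- than in Grn+/+ mice, which is the question of the series title. No gene was called with edgeR (0 of 18239, 434 at an unadjusted p under 0.05), against 3 with DESeq2 and 0 with limma voom. For Tardbp the difference between backgrounds was −0.02 on the log2 scale (95% interval −0.16 to 0.11), for Gid4 −0.05 (−0.16 to 0.07), for Mapt −0.06 (−0.14 to 0.02) and for Grn 0.14 (−0.31 to 0.59). Rarres2 had a smaller transgene effect in Grn+/- mice (difference −0.77, 95% interval −1.29 to −0.24, edgeR unadjusted p = 0.00861), which failed the correction over all genes (adjusted p = 0.9999) and over the 25 named genes (0.215). For Rnd2 the difference was −0.16 (edgeR unadjusted p = 0.0203; 0.254 over the named genes). Among the genes of smallest p were Gm13031 (−0.96), Ip6k3 (−0.95) and the protocadherin Pcdhb13 (0.65). Over genes above 10 CPM the median 95% interval of the interaction reached 0.156 to each side on the log2 scale, a 1.11-fold difference.

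Oligodendrocyte genes showed the widest difference between backgrounds among the lists. The mean centred log2 CPM of 19 oligodendrocyte markers was −0.25 ± 0.43 in Grn+/+ mice without and 0.38 ± 0.42 with the transgene, and −0.01 ± 0.77 and −0.13 ± 0.58 in Grn+/- mice (n = 6 each). The median interaction was −0.85 (camera adjusted p = 6.72e-15, adjusted p = 0.362 with an estimated correlation). Interferon response genes (median −0.32; 4.33e-06, adjusted p = 0.362 with an estimated correlation) and oligodendrocyte precursor markers (−0.17; 5.08e-06, adjusted p = 0.362 with an estimated correlation) also had a lower transgene effect in Grn+/- mice. Of the 8 lists called, 0 held with an estimated correlation, and fry called 0. For transcript usage 1 gene was called, Mbp, the myelin basic protein gene (edgeR adjusted p = 0.000689; limma 0.761). Its long transcript held 13.3% ± 5.72, 7.63% ± 2.53, 11.1% ± 5.54 and 11.1% ± 5.64 of the gene (n = 6 each) in Grn+/+ mice without and with the transgene and in Grn+/- mice without and with it.

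Mice with both changes, set against mice with neither, differed in Grn, Tardbp and 12 other genes. Of the 14 called, 3 were higher and 11 lower: Gid4 (log2 change 0.33, edgeR adjusted p = 0.000554), Rnd2 (0.25, 0.0285) and Spop (0.17, 0.0285) rose, and Grn (−0.93, 0.0246), Tardbp (−0.55, 2.09e-06), Mapt (−0.20, 0.00230) and Atp6v0e2 (−0.22, 0.00216) fell. Pot1a (−0.40, 0.0285), Tmem8b (−0.24, 0.0376), Scrn1 (−0.22, 0.0436), Ppm1a (−0.18, 0.0202) and Kif3c (−0.16, 0.0368) were also lower. Gm16485 (−0.46, 0.0202) and C130046K22Rik (−1.04, 0.0368) fell outside the naming rule. Gid4 measured 72.4 ± 3.49 and 90.8 ± 5.12 CPM and Mapt 564 ± 5.79 and 489.8 ± 23.6 CPM in mice with neither and both (n = 6 each). The number of calls was 4 without replicate 4 of the group with both changes or replicate 5 of the group with neither, and 16 without replicate 5 of the transgenic Grn+/+ group, whose mice share the fit. Scrn1, Tmem8b, Kif3c and C130046K22Rik lost their calls in 20, 15, 14 and 14 of 24 such fits, and Ppm1a turned to 0.020 (adjusted p = 0.923) with length-scaled TPM counts, where Rnd2, Spop, Pot1a, Tmem8b, Kif3c and C130046K22Rik lost their calls. The count was 92 with DESeq2, 33 with surrogate variables, 3 with age as a factor (Tardbp, Gid4 and Atp6v0e2) and 2 in a fit to these groups alone.

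The transgene effect did not differ detectably between males and females in any gene. With edgeR 0 of 18239 genes were called for the difference (749 at an unadjusted p under 0.05), against 2 with DESeq2 and 0 with limma voom. The genes of smallest p were Parp9 (log2 difference 0.80), the sialyltransferase gene St8sia4 (−0.46), the lysosomal gene Cln3 (0.35), the pigment cell gene Dct (−3.90, with single libraries between 0.173 and 5.50 CPM) and Zfp977, each with an edgeR adjusted p of 0.954. Zfp977 was at 0 in all mice of some sex and genotype groups, so it is given without a fold. In simulated data of this design 68% of 1.5-fold and 80% of 2-fold differences were recovered.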

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

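The tests of transcript usage and gene lists without replicate 2 of the transgenic Grn+/+ mice were chosen only after the result was seen. The main usage and list tests and the splits in this part were fixed beforehand. Genes screened for outlying libraries were Grn, Tardbp, Thy1 and the called genes, and the called genes were known only from the results. Replicate 2 of the transgenic Grn+/+ mice stands apart from the other 5 mice of its group in how its reads spread over transcripts. It lists 40188 transcripts above 0, 1402 transcripts with up to 5 reads (11257 to 14697 in the other 23 libraries) and 17669 genes above 0, at 97736984 reads. Its median absolute log2 difference from the other replicates, 0.126, is the highest of its group. Without it the usage calls were 15 for the average transgene effect and 2 for the interaction, and the lists called were 12 and 7. No biological explanation was tested for this library.

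Single mice stood far from the other 5 of their group in 8 more measures. In nontransgenic Grn+/+ mice, replicate 1 held 85.1 M reads (66.4 to 72.8 M in the others), and replicate 2 had 1.17% of its reads on transcripts without a gene and 2.29 CPM of C130046K22Rik. In nontransgenic Grn+/- mice, replicate 3 listed 69214 transcripts above 0 (67858 to 68214 in the others), with Grn at 13.8 CPM and the phosphatase gene Ppm1a at 307.6 CPM. Replicate 2 of that group had Rarres2, the chemerin gene, at 3.42 CPM. Replicate 6 of the transgenic Grn+/- mice had the GTPase gene Rnd2 at 75.9 CPM. In all, 11 of 122 groups of 6 values held such a library, where chance gives 1 in 20, or 6.1.

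Oligodendrocyte, interferon and ribosomal genes responded differently to the transgene in Grn+/- and Grn+/+ mice under the preset correlation of the list test. The median log2 differences between the transgene effects were −0.85 for oligodendrocyte markers, −0.32 for interferon response genes, −0.17 for oligodendrocyte precursor markers, −0.080 for ribosomal protein genes, −0.024 for lysosomal genes, 0.10 for excitatory neuron markers, 0.083 for cholesterol synthesis genes and 0.041 for synaptic genes. The camera adjusted p-values were 6.72e-15, 4.33e-06, 5.08e-06, 4.74e-07, 0.0338, 0.00774, 0.00127 and 0.0345 in that order, and all 8 calls were lost with an estimated correlation, where the adjusted p was 0.362 or 0.760. Of 50 splits of the libraries, 26 called as many lists as the real 8, with up to 16 in the others, so chance is not excluded. Usage of Mbp transcripts differed between backgrounds at an edgeR adjusted p of 0.000689, the 1 usage call for the interaction, and 28 of 30 splits gave as many calls, with up to 8.

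Among 1785 mouse transcripts that had no gene in the annotation used, 1 was called for the average Grn effect. It had a log2 change of 3.45 (SE 0.618, edgeR adjusted p = 0.0278), with 0.0285 and 0.0228 CPM in Grn+/+ mice without and with the transgene and 0.254 and 0.341 CPM in Grn+/- mice (n = 6 each), and 33 transcripts had an unadjusted p under 0.05.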

How the results depend on the processing

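The usage fit by quasi-likelihood, the usage and list tests without replicate 2 of the transgenic Grn+/+ mice, and the splicing target list without Tardbp were chosen only after the result was seen; the other tests here were planned. No paired analysis was possible because replicate numbers were given in listed order and pair no mice. Age as a factor compares mice of equal age, but 4 of the 6 nontransgenic Grn+/- mice have ages that no other group holds, so under it every comparison with that group rests on its replicates 2 and 3, and replicate 3 was low in Grn (13.8 CPM). Compared as single genes, the ratios of Grn and Tardbp between groups kept their direction and side of the threshold as TPM, with age as a linear term and with DESeq2. Among all genes the call of Grn without the transgene was lost with linear age (log2 change −0.98 before, −0.96 after, edgeR adjusted p = 0.177) and with age as a factor (−1.42, 0.505), and that of Tardbp in Grn+/- mice with age as a factor (−0.53 before, −0.54 after, 0.259). RLE scaling, a filter of CPM 1 and the model without sex moved no gene count by over 1.5 times. Of the named-gene results under other settings, 2569 stayed on their side of the threshold, 375 lost the call, 15 gained it and 2 turned. The 2569 include genes called in neither fit, whose changes of sign were counted as staying. The 2 that turned were Ppm1a under length-scaled TPM counts. It stood at 0.065 for the average transgene effect (edgeR adjusted p = 0.556) and 0.020 for both against neither (edgeR adjusted p = 0.923), with log2 changes of −0.12 and −0.18 otherwise. Length-scaled counts weigh transcripts by length and the use of Ppm1a transcripts shifted, which may account for the turn, but this was not tested. Tardbp kept its call for the average transgene effect in every alternative, at log2 changes of −0.77 to −0.51. With edgeR and age as a factor, Tardbp and Atp6v0e2 kept theirs (−0.52, adjusted p = 0.000539; −0.22, adjusted p = 0.0286), while the other 18 lost theirs with their sign kept, Gid4 at 0.27 before and after, Bsn at −0.28 and −0.20; besides those few mice, fewer residual degrees of freedom and a litter or cohort shared at equal age, which the labels do not give, may have ended the calls, and none of these was tested.

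Gene counts moved as follows, in the order transgene in Grn+/+, transgene in Grn+/-, Grn without and with the transgene, both against neither, interaction, average transgene, average Grn and sex difference. DESeq2 called 29, 10, 6, 5, 92, 3, 61, 9 and 2 genes where edgeR called 6, 4, 2, 1, 14, 0, 20, 4 and 0. Among them were 11 of the 14 for both against neither and all of the others. Of the 14, Pot1a, Gm16485 and C130046K22Rik had no adjusted p with DESeq2, so their calls were not compared. With surrogate variables the counts were 13 and 9 for the transgene by background, 3 for Grn with it, 33 for both, 41 for the average transgene (18 of the 20 shared) and 7 for average Grn. Fits to only the 2 groups called 1, 1, 0, 0 and 2, with fewer libraries to estimate the spread. Without a low-count filter the counts were 2 for the transgene in Grn+/-, 0 for Grn with it and 9 for both. Age as a linear term gave 2 for the transgene in Grn+/- and 0 for Grn without it, and age as a factor 0, 0 and 0 for the transgene in Grn+/- and for Grn on either background, 3 for both, 2 for the average transgene and 1 for average Grn. Length-scaled TPM counts gave 2 for the transgene in Grn+/-, 0 for Grn with it and 7 for both, and voom gave 2 for Grn with it. Beside these zeros, edgeR's unadjusted p was under 0.05 for 207 genes (transgene in Grn+/-, age factor), 807, 445 and 1225 (Grn without the transgene: age, age factor, 2 groups) and 1276, 571, 767 and 258 (Grn with it: no filter, age factor, length-scaled counts, 2 groups). The cause of these shifts was not tested.

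Leaving out each library gave 4 to 7 genes for the transgene in Grn+/+ (4 without replicate 4 of the mice with neither change), 2 to 4 in Grn+/- (2 in 10 of 24 fits), 0 to 3 for Grn without the transgene (0 in 17 fits), 1 to 2 with it (2 without replicate 2 of the transgenic Grn+/+ or replicate 3 of the nontransgenic Grn+/- mice), 4 to 16 for both, 0 to 0 for the interaction and for sex, 14 to 22 for the average transgene and 4 to 6 for average Grn. For both, 4 came without replicate 4 of the mice with both or replicate 5 of the mice with neither. Of the average transgene calls, Clns1a was lost in 19 of 24 such fits, Bsn in 18, Ap2m1 in 12, Tcte1 in 8 and Trbc2 in 7. Usage counts were 44 with limma for the average transgene (14 otherwise) and 2 for the interaction (1 otherwise); the quasi-likelihood fit gave 1, 1, 3 and 2 for the average transgene, average Grn, both and interaction (14, 5, 6 and 1 otherwise). With no minimum share usage gave 2 for Grn and 4 for the interaction, with 10% it gave 0 for the interaction (edgeR; 79 genes at an unadjusted p under 0.05), and with age 3 for Grn and 2 for the interaction. Without replicate 2 of the transgenic Grn+/+ mice usage gave 15, 8, 10 and 2. Lists called at the preset correlation were 15, 10, 20, 7, 12, 8, 15 and 18 in the order above; with an estimated correlation they were 1, 2, 1, 0, 2, 0, 2 and 1, with fry 2, 2, 1, 1, 4, 0, 2 and 1, and with age 14 for the interaction. Without replicate 2 of the transgenic Grn+/+ mice they were 16, 8, 20, 11, 12, 7, 12 and 16. At this depth edgeR recovered 68% of simulated 1.5-fold interactions, so smaller ones are not excluded.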

Other observations

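The tests of neighbouring genes on chromosomes 11 and 6 and of the Tardbp transcripts were chosen only after the result was seen; the counts of other splits were planned. Between mice with both changes and mice with neither, 12 lists were called at the preset correlation and 2 with an estimated correlation, and 14 of 50 splits of the libraries called as many, so chance is not excluded for their number. TDP-43 splicing targets were lower (median log2 change −0.08, 15 of 20 below 0, 5 lower adjusted over the list alone; camera adjusted p = 7.95e-10, adjusted p = 0.00286 with an estimated correlation), with Tardbp and Mapt among the members, and without both the unadjusted p with an estimated correlation was 0.0135. Mitochondrially encoded genes, which carry the respiratory chain subunits made in the organelle, were higher (median 0.17, 12 of 13 above 0, 9 higher adjusted over the list alone; 1.99e-10, adjusted p = 0.0806 with an estimated correlation). Ribosomal protein genes (median 0.12, 34 of 34 above 0; 7.80e-19, adjusted p = 0.220 with an estimated correlation) and mural and meningeal markers (median 0.49, 16 of 16; 1.10e-05, adjusted p = 0.303 with an estimated correlation) were higher. Long-intron targets (median −0.09, 18 of 19 below 0; 8.31e-07, adjusted p = 0.0806 with an estimated correlation) and synaptic genes (median −0.09, 28 of 30 below 0; 3.25e-06, adjusted p = 0.206 with an estimated correlation) were lower. Reactive astrocyte genes (median 0.29, 19 of 20 above 0; 0.000412, adjusted p = 0.303 with an estimated correlation) and blood cell genes (median 1.27, 7 of 7; 0.00190, adjusted p = 0.303 with an estimated correlation) also stood higher.

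Neuronal and glial lists were also called within single backgrounds at the preset correlation, and lost these calls with an estimated one. In Grn+/+ mice the transgene went with lower excitatory neuron markers (median −0.10, 14 of 14 below 0; camera adjusted p = 0.00170, adjusted p = 0.242 with an estimated correlation) and synaptic genes (−0.08, 30 of 30; 1.15e-05, adjusted p = 0.242 with an estimated correlation). In transgenic mice the Grn genotype went with lower oligodendrocyte markers (median −0.51; 9.54e-11, adjusted p = 0.587 with an estimated correlation), a comparison in which 26 of 50 splits called as many lists. Without the transgene the Grn genotype went with higher activated microglia genes (median 0.23; 1.28e-05, adjusted p = 0.221 with an estimated correlation). Their mean centred log2 CPM overlapped, at −0.37 to 0.13 in nontransgenic Grn+/+ and −0.30 to 0.90 in nontransgenic Grn+/- libraries (n = 6 each). The highest Grn+/- library thus lay far above its group mean of 0.14. Transcript usage was called for 5 genes by average Grn genotype, Pcdhgc4 (edgeR adjusted p = 2.60e-07), the polycomb gene Eed (0.000393), Abhd4 (0.00677), the transporter gene Slc6a12 (0.0481) and the collagen gene Col7a1 (0.0481), with 0 of them shared with limma or the quasi-likelihood fit. Without replicate 2 of the transgenic Grn+/+ mice Abhd4 went to 0.997 and Col7a1 to 0.0705, and 10 of 30 splits of the libraries called as many genes. For both against neither it was called for 6 genes, led by Pcdhgc4 (7.32e-22) and Ppm1a (9.55e-14), followed by Eed (0.00172), Lpin3 (0.0262), Leng8 (0.0381) and 3110039I08Rik (0.0381), with 5 of 30 splits calling as many. Of these, Lpin3 and Ppm1a alone were shared with limma, where Pcdhgc4 stood at 0.288 and Eed at 0.955, and 0 with the quasi-likelihood fit.

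Genes that differ with Grn genotype cluster beside Grn on chromosome 11. Of 219 tested genes within 5 Mb of Grn, 17 (7.76%) had an unadjusted p under 0.01, against at most 4.88% in 247 windows elsewhere. All 3 called genes besides Grn, the tau gene Mapt, Rnd2 and C130046K22Rik, lie there. Reads of Grn counted to the overlapping gene Fam171a2 cannot be the whole cause, because 16 of these genes do not overlap Grn. Donor-strain DNA carried along with the targeted allele may account for the cluster, a hypothesis in which lower Mapt would mark the chromosome segment and not the loss of progranulin; an effect of progranulin itself on these genes stays open, since the strain history is not given in the sources used here.

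Genes on part of chromosome 6 differ with the transgene. In the window from 40 to 50 Mb, 12 of 61 genes (19.7%) had an unadjusted p under 0.01, the highest of 249 windows; the window from 20 to 30 Mb was next at 11.6%, that from 50 to 60 Mb stood at 8.20% and that from 30 to 40 Mb at 1.32%. The 5 called genes, Pot1a, Trbc2, Atp6v0e2, Rarres2 and Scrn1, span 28.8 Mb, which is too wide for an effect of an insertion on its nearest neighbours alone. Donor-strain DNA around an insertion on chromosome 6 may account for them but cannot be told apart from an effect of TDP-43, because the window in between was low and neither the insertion site nor the donor strain is given in the sources used here.

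Mouse Tardbp is lower in transgenic mice. The share of its nonsense-mediated decay transcript with the spliced 3' untranslated region gained 6.81 percentage points, and the transcript's own CPM rose from 10.7 to 15.7 in Grn+/+ and from 10.7 to 12.8 in Grn+/- mice (exact permutation p = 0.0152 and 0.0173, n = 6 per group), which is consistent with autoregulation, in which TDP-43 protein lowers its own messenger by splicing. The other 2 decay transcripts fell, ENSMUST00000190696.7 from 7.72 to 2.59 CPM and ENSMUST00000147391.3 from 6.57 to 4.31 CPM in Grn+/+ mice (exact permutation p = 0.0021645 each, n = 6 per group), so decay transcripts did not rise in general. Reads shared between the human and the mouse transcript may contribute: mouse Tardbp lost 43.8 CPM where the human transcript held 74.8 ± 5.67 CPM (n = 12), a ratio of 0.585, and this cannot be told apart without the reads. Both may act together.

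Other splits of the libraries into groups of the same sizes were tried, 50 for genes and lists and 30 for usage, the real one included. As many genes as in the real split were called in 1 of 50 for the transgene in Grn+/+ (6 real, 2 the highest other). It was 1 of 50 also for the transgene in Grn+/- (4, 1), Grn without the transgene (2, 0), average Grn (4, 1) and both against neither (14, 1). Each lies under 1 in 20. These counts hold Grn, mouse Tardbp or both, whose levels follow the genotype, so part of each was fixed in advance. Leaving out 1 library ended the calls of Grn and Rnd2 without the transgene in 19 and 18 of 24 fits. For the average transgene 2 of 50 splits reached 20 with the real one included, which also lies under 1 in 20, but the other called 184, which points to a structure of the samples whose source was not tested. Chance was not excluded for Grn in transgenic mice (3 of 50; 1, 1). For the interaction (50 of 50; 0, 4) and the sex difference (50 of 50; 0, 1) the real split called 0 genes, so every split reaches it and the count says nothing on chance. For usage the average transgene count was reached by 1 of 30 splits, the real one (14, 10), which lies under 1 in 20. That count holds Tardbp, whose level follows the genotype, and the quasi-likelihood fit called 0 of the 14. On simulated counts the usage test made 26 false calls. Chance is therefore not excluded for the other usage calls. Nor was it excluded for average Grn (10 of 30, with 5 real and 9 the highest other), both (5, with 6 and 9) or the interaction (28, with 1 and 8). As many lists as in the real split were called in 2 of 50 for the transgene in Grn+/+ (15 real, 16 the highest other) and the average transgene (15, 16). For Grn without the transgene it was 1 of 50 (20, 19), and for average Grn 2 (18, 18). The 34 lists include the transgene and target genes, whose levels follow the genotype, and other splits called about as many. Chance is therefore not excluded for the other lists. With an estimated correlation 1, 2, 1 and 1 lists were called in these comparisons. Nor was chance excluded for lists with the transgene in Grn+/- (33 of 50, with 10 real and 21 the highest other) or Grn with the transgene (26, with 7 and 13). The same held for the interaction (26, with 8 and 16) and both (14, with 12 and 16).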
